A study of Mus musculus with 6 samples.

How the data were processed

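Gene expression was measured with an Affymetrix 3' expression array in 6 mouse embryos at mid-gestation, 3 called KOF and 3 wild type, which the series describes as littermates of an Rnaseh2b line. What KOF stands for is not given in the sources used here. The sample titles name fetal liver, while the tissue field of the same labels says embryo, and the samples are taken here as fetal liver. Total RNA was extracted with acid guanidinium thiocyanate, phenol and chloroform, then reverse transcribed, amplified and given a biotin label with a commercial kit (Message Amp II-Biotin Enhanced, Ambion), per the labels' protocols. Array scans were not analysed here. The deposited table holds 1 log2 value per probe set and array, which the authors had already summarised from the probes. The summarising method, the scaling between arrays, any background step and the program are not given in the sources used here. The log2 scale was read from the values, which ran from 1.91 to 15.0. Their centring within an array is unknown, and no direction needs to be set because each array holds 1 sample. Medians of the deposited values were 6.09, 6.11 and 6.09 on wild type arrays 1 to 3, and 6.12, 6.14 and 6.10 on KOF arrays 1 to 3. None of the 45101 probe sets had a missing value on the 6 arrays.

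The design, the gene lists, the rule for genes to name and the alternatives were set before the data were examined, apart from those said below to have been added. One rule was that a table whose 10th, 25th, 50th, 75th or 90th percentiles differed by more than 0.1 between arrays would be quantile normalized. The 75th percentile ran from 7.86 to 8.07, so the log2 values were quantile normalized, and the deposited values as they stand became an alternative. Gene names came from the platform annotation, in which 34958 probe sets had exactly 1 gene symbol, 932 had several and 9211 were not listed. Of these, 34754 probe sets were matched by gene identifier to a current gene table, and 0 symbols changed. Each of 18194 genes was represented by its probe set with the highest mean over the 6 arrays, and probe sets with several symbols named no gene. The 4549 genes in the lowest 25% of mean signal were left out of the gene test, which leaves 13645 genes. The table has no detection calls, so no statement on background is made.

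Genes were tested with limma 3.58.1 (lmFit and eBayes, with statmod 1.5.0, in R 4.3.3) as KOF minus wild type over all 6 arrays with no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Only called genes are said to have risen or fallen, apart from list members said to have done so when adjusted over the list alone. The Rnaseh2b value was also given an exact permutation test, in which 3 against 3 arrays cannot go below a two-sided p of 0.1. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01 over all 18194 genes, with Benjamini-Hochberg adjustment over the 32 lists. These lists hold 773 entries, of which 712 were measured. They cover p53 targets, interferon-stimulated genes, inflammation, nucleic acid sensing, DNA repair and replication, mitosis, nucleotide metabolism, cell death, stress and sterol pathways, embryo sex, and the cell types of fetal liver and of neighbouring tissues. Neighbouring lists share up to 4 genes. List calls were set beside camera with an estimated correlation and beside fry, which asks only whether a list's genes move on balance one way. A further form of fry counts changes in either direction.

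Genes to name were Rnaseh2b, Rnaseh2a, Rnaseh2c, Cdkn1a, Ccng1, Mdm2, Ifit1, Isg15 and Cxcl10, then the 12 called genes with the largest change in each direction whose KOF and wild type values did not overlap. Where fewer passed, the genes with the smallest p filled a direction up to 5. From each list came up to 4 called members, or the 2 brightest where none was called. Any other gene named was chosen after its values were seen. Isg15 was not analysed here because its probe set carries several symbols.

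Alternatives were other normalizations, filters, ways to choose a probe set, variance models, array weights, a replicate block, embryo sex as a covariate, other thresholds, other list tests, and each array left out in turn. Control probe sets on the arrays then showed KOF 1 and KOF 2 to differ from the other 4 arrays in their added poly-A RNAs. A block for that shift, KOF 3 alone against the wild type, and a fit without wild type 1 and KOF 2 were added after seeing the data. With the control shift as a block the estimate rests on KOF 3 against the 3 wild type arrays, because the shifted arrays are all KOF, and the lone KOF array is assumed to vary like the others. Gene and list p-values of that fit therefore do not measure the spread between KOF embryos, and its list p-values use the preset correlation.

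The gene test was checked on simulated data for the KOF and wild type comparison of 13645 genes. With the residual spread of the fit, it recovered 56% of genes changed by a log2 of 1 and 95% of those changed by 2, with 7 false calls. With the spread between wild type arrays it recovered 92% and 98%, with 14 false calls. In a simulation of the list test over 18194 genes, a list shifted by 0.5 was called and 0 other lists were. Both simulations drew the noise of each gene and array independently, without the joint shift of KOF 1 and KOF 2. They therefore cannot show how often correlated genes or that shift give false calls. The number of arrays limits the precision of each value. The labels describe littermate embryos, so each array is read as 1 embryo, and p-values measure the spread between those embryos and their processing together.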

Results

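Expression profiles were made from the livers of 3 KOF and 3 wild type littermate embryos of an Rnaseh2b line at mid-gestation, when the fetal liver is the main site of blood formation. Rnaseh2b encodes a subunit of RNase H2, the enzyme that removes single ribonucleotides from DNA and digests the RNA strand of RNA-DNA hybrids. Mutations of its human counterpart are among the causes of Aicardi-Goutières syndrome, an inherited inflammatory disease with raised interferon signalling. The comparison asks which transcripts differ in fetal liver between KOF embryos and wild type littermates. Values below are log2 signals after quantile normalization, and differences are KOF minus wild type with n = 3 embryos per group unless stated. The genes and lists to report were fixed before the data were examined, and genes named besides those the rule gives (Aen, Bbc3, Sesn1, Irf7, Usp18, Rsad2, Oasl2, Samd9l, Adar, Ifih1, Epb42, Timd4, Adgre1, Vpreb1 and others called among the arrays with unshifted controls) were chosen after their values were seen. No 2 arrays were copies of each other, with at most 0.302% of probe sets holding identical deposited values on any pair.

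The Rnaseh2b transcript fell in KOF liver to 5.47% of its wild type level. Its signal was 11.45, 11.43 and 11.32 on the wild type arrays and 7.26, 6.91 and 7.45 on KOF arrays 1 to 3, a log2 difference of -4.19 with an SE of 0.16 (limma adjusted p = 0.000438). The exact permutation test gave a two-sided p of 0.1, the smallest that 3 against 3 allows. Every KOF array lay below every wild type array, so all 6 labels match this transcript. The part of the transcript that its 1 probe set covers, and whether the KOF allele removes it, were not analysed here. Transcripts of the other subunits of the enzyme did not pass the test. Rnaseh2a, the catalytic subunit, had a log2 difference of 0.25 (SE 0.19, adjusted p = 0.366), with 0.41, 0.52 and -0.16 on KOF 1 to 3. Rnaseh2c had one of 0.19 (SE 0.16, adjusted p = 0.423), with 0.37, 0.32 and -0.13. Without KOF 3 both were called higher, at 0.46 (adjusted p = 0.001, in a range of 0.000135 to 0.757 over the alternatives) and 0.35 (adjusted p = 0.00394, 0.000279 to 0.798). That fit called 9902 of 13645 genes. It sets only KOF arrays with shifted controls against wild type, so it cannot tell KOF from that shift.

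Over all genes, KOF 3 lay with the wild type arrays. The first principal component held 80.9% of the variance, with scores of -23.6, -23.0 and -29.9 for the wild type arrays, 47.1 and 51.9 for KOF 1 and KOF 2, and -22.4 for KOF 3. Probe sets for the bacterial transcripts dap, lys, phe and thr, poly-A control RNAs that are added to a sample before labelling, followed the same split. Over 24 such probe sets the median shift from the wild type mean was 1.15 on KOF 1 and 1.07 on KOF 2, against -0.06 on KOF 3. The 3 probe sets for 18S ribosomal RNA shifted by 1.21, 1.16 and 0.10 on KOF 1 to 3. Hybridisation controls, added after labelling, shifted by -0.10, 0.10 and 0.05. No label names a batch, and whether the shift lies in processing or in the RNA of those embryos is left open. Values from the 4 arrays with unshifted controls, which are KOF 3 minus the wild type mean, are given below beside the pooled ones for called lists, for called genes and for each named gene in which they have the other sign, as is a fit with the control shift as a block. Both rest on KOF 3 alone, so their p-values and calls, also those of lists, are not evidence across KOF embryos.

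**Figure D1:**
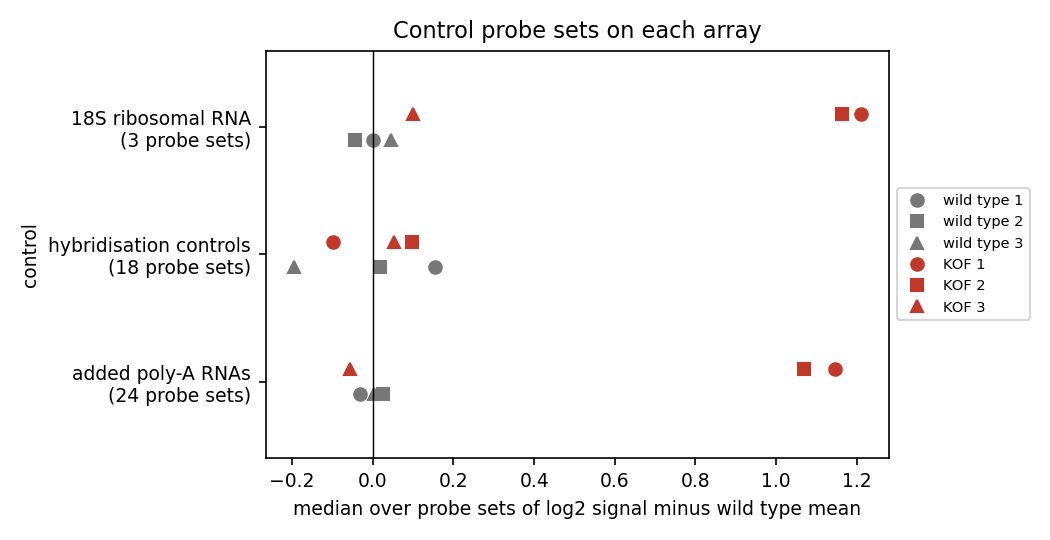
Median shift of 3 kinds of control probe sets on each of the 6 arrays, as log2 signal minus the wild type mean, with grey symbols for wild type and red for KOF embryos. KOF 1 and KOF 2 stand at 1.15 and 1.07 for the added poly-A RNAs and at 1.21 and 1.16 for 18S ribosomal RNA, while KOF 3 stands at -0.06 and 0.10.

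Besides Rnaseh2b, 6 genes differed between the groups, all higher in KOF liver, and 4 of these are in the fixed list of p53 targets. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose 10.6-fold (log2 3.40, SE 0.19, adjusted p = 0.00276), from 7.98 ± 0.33 (SD) in wild type to 11.39 ± 0.15 in KOF. Phlda3, an inhibitor of Akt signalling, rose 5.25-fold (log2 2.39, SE 0.18, adjusted p = 0.0125). Zmat3, a zinc finger RNA-binding protein, rose 3.79-fold (log2 1.92, SE 0.16, adjusted p = 0.0136), and Psrc1, a microtubule-associated protein, rose 2.61-fold (log2 1.38, SE 0.11, adjusted p = 0.0125). The other genes were Hspa1b, an inducible heat shock protein of the Hsp70 family, at 2.99-fold (log2 1.58, SE 0.12, adjusted p = 0.0126), and Cpt1c, a carnitine palmitoyltransferase, at 2.74-fold (log2 1.46, SE 0.14, adjusted p = 0.0336). Hspa1b has the near-identical paralog Hspa1a, and its probe sets may not separate them.

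The rises were of similar size on each KOF array, which follows in part from how the genes were chosen. A gene that differed between KOF arrays had a wider residual spread and was less likely to be called. Cdkn1a stood above the wild type mean by 3.47, 3.50 and 3.24 on KOF 1 to 3, Phlda3 by 2.63, 2.52 and 2.02, Zmat3 by 2.14, 2.01 and 1.61, and Psrc1 by 1.42, 1.43 and 1.30. Hspa1b stood at 1.43, 1.70 and 1.61 and Cpt1c at 1.53, 1.61 and 1.23. A fit with the control shift as a block gave limma adjusted p-values of 0.00069 for Cdkn1a, 0.000163 for Phlda3, 0.000327 for Zmat3, 0.000427 for Psrc1, 0.00181 for Hspa1b, 0.00195 for Cpt1c and 0.000121 for Rnaseh2b. Over the alternatives read for single genes, the adjusted p ran from 2.38e-07 to 0.108 for Cdkn1a, up to 0.186 for Zmat3, Psrc1 and Hspa1b, up to 0.176 for Phlda3, and up to 0.361 for Cpt1c. For Rnaseh2b it ran from 3.05e-09 to 0.0375. These ranges leave out the fit without wild type 1 and KOF 2, in which Rnaseh2b alone was called.

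**Figure D2:**
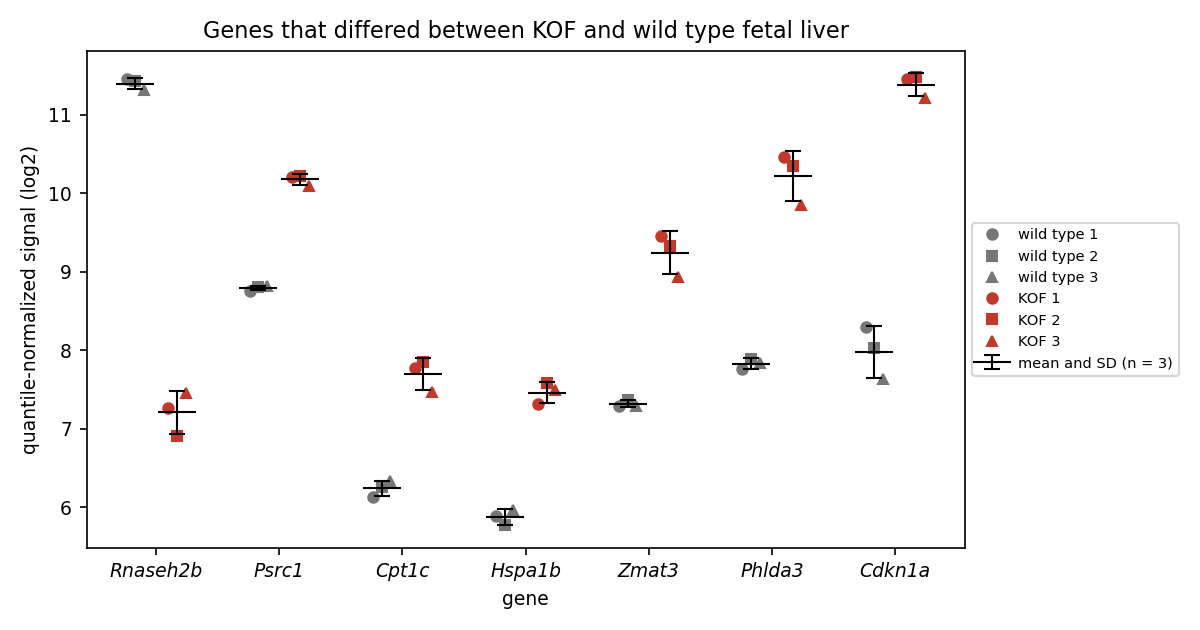
Quantile-normalized log2 signal of the 7 genes that differed between KOF and wild type liver, with 1 symbol per embryo (grey, wild type, and red, KOF) and black bars for the mean and SD of 3 embryos. Rnaseh2b is at most 7.45 on the KOF arrays and at least 11.32 on the wild type arrays, and the other 6 genes are higher on every KOF array.

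In all, limma called 7 of 13645 genes, and 3644 had an unadjusted p under 0.05, of which 1908 were higher and 1736 lower in KOF. The groups did not overlap for 28.4% of genes (2202 higher and 1679 lower in KOF). Chance gives 10% only if all arrays are exchangeable. KOF 1 and KOF 2 moved together, so the share above 10% cannot be read as an effect of KOF. Rnaseh2b was the only gene called lower. Those with the next smallest p in that direction did not pass. They were Runx1t1, a transcriptional corepressor (log2 -1.81, adjusted p = 0.0926), C9, a complement component made by liver (-0.93, 0.168), Aqp1, the water channel of red cells (-1.18, 0.185), and Xpo7, a nuclear transport receptor (-0.76, 0.185). The call count moved with the arrays used. Leaving out KOF 3 gave 9902 called genes, leaving out wild type 1, wild type 2, wild type 3, KOF 1 or KOF 2 gave 2 each time (Rnaseh2b and Cdkn1a), and the control shift as a block gave 128, which included all 7. Of 70 named genes not called with all arrays, 44 were called without KOF 3, and in 24 of the 76 named genes besides Rnaseh2b KOF 3 lay on the other side of the wild type mean from the pooled difference. The fit without KOF 3 called 72.6% of all genes tested (6144 higher and 3758 lower), so a call in it is common. It also cannot tell KOF from the control shift, which holds for each call without KOF 3 given below.

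The p53 target list was higher in KOF liver. Of 39 members tested, 4 rose, 0 fell and 35 did not pass, and 14 rose and 1 fell when adjusted over the list alone. The median over 42 measured members was 0.38, 0.33 and 0.26 on KOF 1 to 3, and 18 lay higher and 4 lower on all KOF arrays than on all wild type arrays. At an unadjusted p under 0.05 there were 14 higher and 3 lower. Camera gave an adjusted p of 0.000119, which became an adjusted p of 0.128 with an estimated correlation, while fry gave 0.000448. Among members that did not pass over all genes were Aen, an apoptosis-enhancing nuclease, at 0.75 (SE 0.12), and Bbc3, the pro-apoptotic protein Puma, at 0.89 (SE 0.16). Sesn1, a sestrin, was the member that fell when adjusted over the list alone, at -0.61 (SE 0.13). Mdm2, the ubiquitin ligase of p53, had a difference of -0.11 (adjusted p = 0.696), with -0.29, -0.39 and 0.33 on KOF 1 to 3. Without KOF 3 it was called lower at -0.34 (adjusted p = 0.00335, in a range of 0.00114 to 0.964 over the alternatives). Ccng1, cyclin G1, had one of 0.45 (adjusted p = 0.444) and stood at -0.05 and -0.07 on KOF 1 and KOF 2 and at 1.48 on KOF 3. Among the arrays with unshifted controls 8 of the 39 genes were called, all higher, namely Phlda3, Zmat3, Psrc1, Ccng1, Cdkn1a, Trp53inp1, Pmaip1 and Aen (of which Ccng1, Trp53inp1 and Pmaip1 lay below the wild type mean on both KOF 1 and KOF 2), with a list median of 0.30 and a camera adjusted p of 6.21e-16 with the control shift as a block. Without KOF 3 the camera adjusted p was 0.247, the highest of its alternatives, while the value with the block rests on KOF 3 alone.

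Interferon-stimulated genes as a list were also higher in KOF liver, most of all on KOF 3, though none of the 41 members tested passed alone in limma. At an unadjusted p under 0.05 there were 18 higher and 0 lower, and adjusted over the list alone 11 rose. The median over 43 measured members was 0.19 on KOF 1, 0.20 on KOF 2 and 1.04 on KOF 3, and 20 of them lay higher on all KOF arrays than on all wild type arrays. Camera gave an adjusted p of 1.40e-05, which became an adjusted p of 0.706 with an estimated correlation, and fry gave 0.234. The members with the smallest p were Lgals3bp, a secreted galectin-binding glycoprotein, at 1.08 (SE 0.12, adjusted p = 0.0639), and Ifi35 at 1.13 (SE 0.13, adjusted p = 0.0688). On KOF 1 to 3, Lgals3bp stood at 1.04, 1.15 and 1.04, Ifi35 at 1.07, 1.01 and 1.32, and Irf7, the transcription factor that amplifies interferon production, at 1.00, 1.03 and 2.76. Ifit1, an antiviral protein that binds foreign RNA, stood at -0.05, -0.16 and 3.61 (pooled log2 1.13, adjusted p = 0.417), and the chemokine Cxcl10 at 0.31, 0.82 and 1.73 (pooled 0.96, adjusted p = 0.185). Among the arrays with unshifted controls 27 of the 41 genes were called, all higher, with a list median of 1.09 and a camera adjusted p of 9.63e-65 with the control shift as a block (9.63e-65 to 0.826 over the alternatives). Of these, Usp18 was higher by 2.81, Irf7 by 2.76 and Oasl2 by 2.41, and all 3 also lay above the wild type mean on KOF 1 and KOF 2. Of the 27 genes, 10 lay below the wild type mean on both KOF 1 and KOF 2, and 5 of these were called lower without KOF 3. Rsad2 stood at -0.18, -0.25 and 2.46 on KOF 1 to 3 (pooled 0.68, adjusted p = 0.494), and Samd9l at -1.18, -1.43 and 1.09. The list call rested on KOF 3, since without it the camera adjusted p was 0.826, the highest of its alternatives. The value with the block likewise rests on that embryo alone. Isg15 was not analysed here.

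Genes of the nucleic acid sensors and of Aicardi-Goutières syndrome did not differ as a list (camera adjusted p = 0.595), and none of 16 tested members was called by limma, with 3 higher and 1 lower at an unadjusted p under 0.05. Rnaseh2c and Rnaseh2a were its brightest members. Adar, the RNA-editing enzyme, was the member that rose when adjusted over the list alone, at 0.54, 0.63 and 0.80 on KOF 1 to 3. With the control shift as a block the list was called higher (adjusted p = 7.94e-05, in a range of 7.94e-05 to 0.853 over its alternatives), against an adjusted p of 0.853 with an estimated correlation over all arrays. Adar and the RNA sensor Ifih1 were its members called higher in that block fit, but Ifih1 stood at -0.67, -0.78 and 1.56 on KOF 1 to 3 and was called lower without KOF 3 (-0.72, adjusted p = 8.42e-05). The inflammatory cytokines and chemokines did not differ (adjusted p = 0.694), with 0 of 15 tested members called and 4 higher and 1 lower at an unadjusted p under 0.05. Il18 fell when adjusted over the list alone (-0.86), and Ccl2, a chemokine, was called higher among the arrays with unshifted controls (0.57, adjusted p = 0.0353). Nfkbia, an inhibitor of NF-kappaB, had a difference of 0.30 (adjusted p = 0.185), and the chemokine Cxcl1 one of 0.14 (adjusted p = 0.435), or -0.40 on its most variable probe set.

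**Figure D3:**
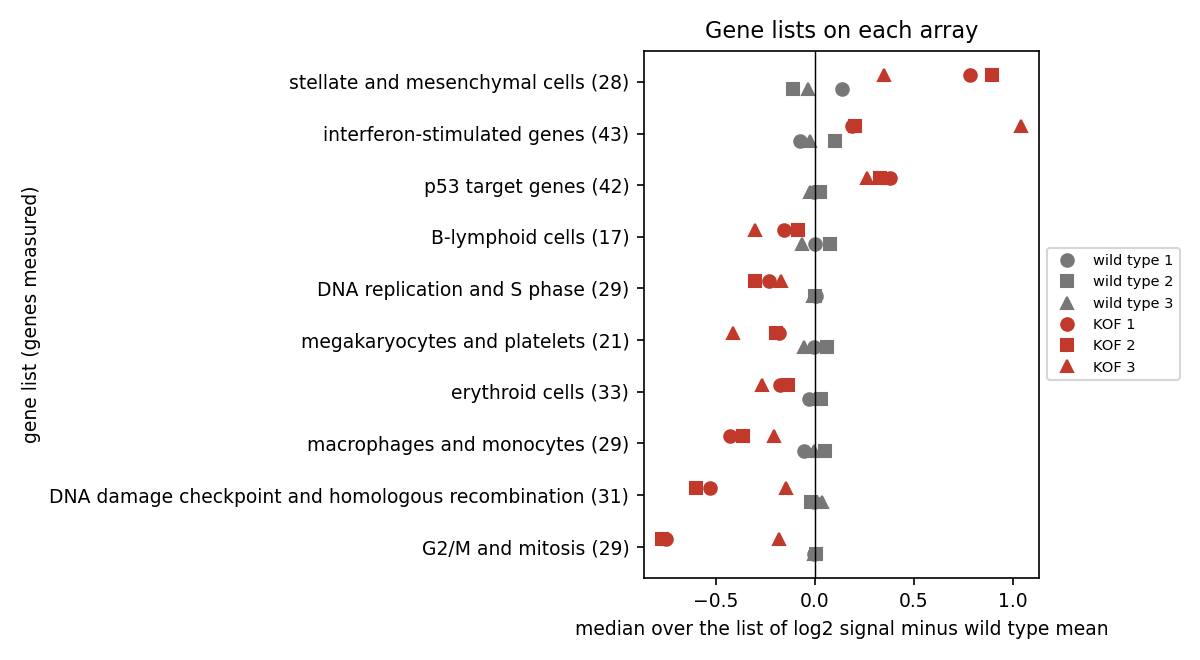
Median of each of the 10 gene lists called by camera on each array, as log2 signal minus the wild type mean, with the number of genes measured in brackets, grey symbols for wild type and red for KOF embryos. KOF 3 stands apart for interferon-stimulated genes at 1.04 against 0.19 and 0.20 on KOF 1 and KOF 2, and nearer to 0 for mitotic genes at -0.18 against -0.75 and -0.77.

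Lists of mitosis, of checkpoint and homologous recombination, and of replication were lower in KOF liver, by more on KOF 1 and KOF 2 than on KOF 3. For mitosis the median was -0.75, -0.77 and -0.18 on KOF 1 to 3, and 21 of 29 members lay lower on all KOF arrays. None of the 29 passed over all genes in limma, 19 were lower at an unadjusted p under 0.05, and 14 fell when adjusted over the list alone (camera adjusted p = 1.27e-07, and an adjusted p of 0.214 with an estimated correlation). Its brightest members were Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, at 0.09 (adjusted p = 0.584, -0.0098 on KOF 3), and the cyclin Ccna2 at -0.58 (adjusted p = 0.185). The checkpoint and homologous recombination list had medians of -0.53, -0.60 and -0.15, with 0 of 31 members called and 16 lower at an unadjusted p under 0.05 (camera adjusted p = 7.01e-06, and an adjusted p of 0.303 with an estimated correlation). Of its brightest members, Rpa1, which coats single-stranded DNA, had a difference of -0.22 and the histone variant H2ax one of 0.00 (0.17, 0.23 and -0.39 on KOF 1 to 3). The replication list had medians of -0.23, -0.30 and -0.17, with 0 of 29 members called and 14 lower at an unadjusted p under 0.05 (camera adjusted p = 0.000396, and an adjusted p of 0.128 with an estimated correlation). The helicase subunits Mcm7 and Mcm5, its brightest members, had differences of -0.02 and 0.14 (Mcm5 at -0.10 on KOF 3). These depend on the probe set, with 0.08 for Mcm7 and 1.38 for Mcm5 on the most variable one and 0.60 for the mean over Mcm5 probe sets. When adjusted over the list alone 0 genes of the checkpoint list and 0 of the replication list fell. With the control shift as a block the camera adjusted p was 5.36e-06 for mitosis (5.64e-08 to 0.214 over its alternatives), 0.01 for the checkpoint list (2.88e-06 to 0.303) and 5.81e-06 for replication (5.81e-06 to 0.128), with 0 members of each called among the arrays with unshifted controls.

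The remaining lists of DNA metabolism did not differ. Genes of ribonucleotide excision and RNA-DNA hybrids had a camera adjusted p of 0.237, with 1 higher and 4 lower of 20 at an unadjusted p under 0.05 and 0 called. Pcna, the sliding clamp, had a difference of -0.42 (adjusted p = 0.185), and the flap endonuclease Fen1 one of -0.14 (adjusted p = 0.375). Mismatch, base and nucleotide excision repair had a camera adjusted p of 0.595, with 2 higher and 5 lower of 21 at an unadjusted p under 0.05 and 0 called, and Apex1 and Ddb1 stood at 0.34 and 0.21 (Ddb1 at -0.013 on KOF 3). Deoxynucleotide metabolism had a camera adjusted p of 0.536, with 5 higher and 3 lower of 21 at an unadjusted p under 0.05 and 0 called. Its brightest members were Nme2 at 0.09 and the ribonucleotide reductase subunit Rrm2 at -0.31 (adjusted p = 0.185). Cell death genes outside the p53 list had a camera adjusted p of 0.726, with 3 higher and 1 lower of 25 at an unadjusted p under 0.05 and 0 called, and Cycs and Mcl1 stood at -0.14 and -0.18 (Cycs at 0.05 on KOF 3).

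Markers of several blood lineages were lower in KOF liver as lists. The erythroid list had medians of -0.18, -0.14 and -0.27 on KOF 1 to 3. None of its 32 tested members passed in limma, 16 were lower and 0 higher at an unadjusted p under 0.05, and 12 fell when adjusted over the list alone (camera adjusted p = 4.79e-08, and an adjusted p of 0.128 with an estimated correlation). Aqp1 stood at -1.06, -0.95 and -1.52, and Epb42, a protein of the red cell membrane skeleton, at -1.58, -1.22 and -0.69. The brightest members, the carbonic anhydrase Car2 and the anion exchanger Slc4a1, had differences of -0.36 (adjusted p = 0.185) and -0.08 (adjusted p = 0.668). Embryonic globins, made by the earlier yolk sac red cells, did not differ as a list (camera adjusted p = 0.351), with 1 of 3 higher at an unadjusted p under 0.05 and 0 called over all genes. Hba-x was the member that rose when adjusted over the list alone, at 1.14. Hbb-y had a difference of 0.27 and Hbb-bh1 one of -0.06, or 0.09 on its most variable probe set.

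The macrophage list had medians of -0.43, -0.36 and -0.21 on KOF 1 to 3. Of 28 tested members 0 passed in limma, 14 were lower at an unadjusted p under 0.05, and 12 fell when adjusted over the list alone (camera adjusted p = 7.54e-07, and an adjusted p of 0.128 with an estimated correlation). Timd4, a receptor for dying cells on resident macrophages, stood at -0.97, -1.04 and -0.64, and Adgre1, the F4/80 antigen, at -0.98, -1.01 and -0.46. Lyz1 and Cd5l, the brightest members, had differences of -0.54 (adjusted p = 0.187) and -0.38 (adjusted p = 0.185). For megakaryocytes and platelets the medians were -0.18, -0.20 and -0.42, with 0 of 21 called, 9 lower at an unadjusted p under 0.05 and 7 lower when adjusted over the list alone (camera adjusted p = 1.25e-05, and an adjusted p of 0.180 with an estimated correlation). The platelet chemokines Ppbp and Pf4 had differences of -0.82 (adjusted p = 0.185) and -0.24 (adjusted p = 0.197). For B-lymphoid cells the medians were -0.16, -0.09 and -0.30, with 0 of 11 called, 3 lower at an unadjusted p under 0.05 and 2 lower when adjusted over the list alone (camera adjusted p = 0.000119, and an adjusted p of 0.303 with an estimated correlation). Ighm and Cd79b, its brightest members, stood at 0.19 and -0.16 (Ighm at -0.05 on KOF 3, at -0.03 for the mean of its 11 probe sets, of which 7 share a sign, and at -0.68 on the most variable one), and Vpreb1, a surrogate light chain of B cell precursors, stood at -0.60, -0.59 and -0.99. With the control shift as a block the estimates for these lists are those of KOF 3 alone, whose medians are given above. The camera p-values of that fit do not measure the spread between KOF embryos. Over the alternatives the camera adjusted p ran up to 0.128 for erythroid and macrophage genes, 0.180 for megakaryocyte and 0.303 for B-lymphoid genes. Called among the arrays with unshifted controls were Aqp1, Timd4, C1qc, C1qa, Mrc1, Clec4f, Clec1b and Vpreb1, all lower, although C1qa stood at 0.06 and 0.07 on KOF 1 and KOF 2. Without KOF 3 the B-lymphoid list had an adjusted p of 0.0737.

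Other blood lists did not differ by camera, and limma called 0 of their members. Stem and progenitor genes had an adjusted p of 0.422, with 1 higher and 6 lower of 21 at an unadjusted p under 0.05, and the transcription factors Lmo2 and Myb stood at -0.46 and -0.42 (Myb at -0.61, -0.79 and 0.15 on KOF 1 to 3). Granulocyte genes had an adjusted p of 0.552, with 2 higher and 2 lower of 19, and Mpo and S100a8 stood at 0.07 and -0.41 (-0.03 and 0.05 on KOF 3). T and NK cell genes also had an adjusted p of 0.552, with 1 higher and 0 lower of 10, and Zap70 and Nkg7 stood at 0.20 and 0.39 (Zap70 at -0.11 on KOF 3). Mast cell, basophil and eosinophil genes had an adjusted p of 0.351, with 0 higher and 1 lower of 10 (Mcpt8 fell when adjusted over the list alone), and Prg2 and Mcpt8 stood at -0.43 and -0.75 (Prg2 at -0.87, -0.55 and 0.14 on KOF 1 to 3). In the stem cell and granulocyte lists the median, at 0.06 and 0.04, and the mean, at -0.13 and -0.06, differed in sign.

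Stellate and mesenchymal genes were higher in KOF liver as a list, with medians of 0.79, 0.90 and 0.35 on KOF 1 to 3. Of 27 tested members 0 passed over all genes in limma, 16 were higher and 0 lower at an unadjusted p under 0.05, and 13 rose when adjusted over the list alone (camera adjusted p = 7.06e-06, and an adjusted p of 0.303 with an estimated correlation). The collagen genes Col3a1 and Col1a2, its brightest members, had differences of 0.85 (SE 0.19, adjusted p = 0.185) and 1.03 (SE 0.23, adjusted p = 0.185), and each stood higher on KOF 1 and KOF 2 than on KOF 3, where they stood at 0.49 and 0.56. The fit with a control-shift block gave a camera adjusted p of 1.66e-11 (1.09e-11 to 0.303 over the alternatives), with 0 members called. Endothelial genes did not differ as a list (camera adjusted p = 0.306), with 0 of 24 called and 3 higher and 3 lower at an unadjusted p under 0.05. Egfl7 stood at 0.38, with 0.63, 0.51 and -0.0019 on KOF 1 to 3, and Lyve1 at -0.34, with -0.57, -0.62 and 0.17.

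Hepatoblast and hepatocyte genes did not differ as a list (camera adjusted p = 0.591), with 0 of 35 called by limma, and 11 higher and 6 lower at an unadjusted p under 0.05. Adjusted over the list alone, Foxa2 rose (0.70) and Arg1 (-0.88) and Cps1 (-1.40) fell. Albumin (Alb) and the apolipoprotein Apoa2, its brightest members, had differences of -0.21 (adjusted p = 0.289) and -0.03 (adjusted p = 0.871), with 0.0052 and 0.08 on KOF 3. Foxa2 was called higher among the arrays with unshifted controls (0.52, adjusted p = 0.0495). The direction of the list was lower by camera with all arrays, higher by fry, and higher with the control shift as a block, which rests on KOF 3 alone. The list's camera adjusted p ran up to 0.923 over its alternatives, and was 0.856 with an estimated correlation over all arrays. Biliary genes had a camera adjusted p of 0.306, with 1 higher and 0 lower of 7 at an unadjusted p under 0.05 and 0 called, and Cdh1 and Sox4 stood at 0.05 and 0.13 (Cdh1 at -0.07 on KOF 3, Sox4 at 0.53 on its most variable probe set). Markers of neighbouring tissues did not differ by camera, and 0 were called by limma. Neural genes had an adjusted p of 0.835, with 1 higher and 0 lower of 6 at an unadjusted p under 0.05, and Nes and Gap43 stood at 0.33 and 0.31 (Nes at -0.08 on KOF 3). Gut and pancreas genes had an adjusted p of 0.595, with 0 of 9 at an unadjusted p under 0.05, and Lgals2 and Cela1 stood at 0.29 and -0.01. Muscle genes also had an adjusted p of 0.595, with 0 of 15 at an unadjusted p under 0.05, and Tnnc1 and Actc1 stood at -0.02 and 0.94.

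Stress and metabolic lists did not differ by camera over all 6 arrays, and limma called 0 of their members there. Sterol synthesis had medians of 0.25, 0.23 and 0.26 on KOF 1 to 3 and an adjusted p of 0.152. Of its 17 tested members 8 were higher and 0 lower at an unadjusted p under 0.05, and 5 rose when adjusted over the list alone. The farnesyl diphosphate synthase gene Fdps stood at 0.42 (adjusted p = 0.185) and Hmgcs1 at -0.60 (adjusted p = 0.253). Hmgcs1 was at -1.07, -0.99 and 0.25 on KOF 1 to 3, and without KOF 3 it was called lower at -0.90 (adjusted p = 2.87e-05, 7.91e-07 to 0.594 over the alternatives). The control shift as a block brought the adjusted p of this list to 3.50e-12, in a range of 3.50e-12 to 0.951 over its alternatives. That value rests on 1 KOF array at the preset correlation, and the list had an adjusted p of 0.335 with an estimated correlation over all arrays. The unfolded protein and integrated stress response list had an adjusted p of 0.552, with 4 higher and 0 lower of 23 at an unadjusted p under 0.05, and the chaperones Calr and Hspa5 stood at 0.07 and -0.59. Hspa5 was at -0.91, -0.99 and 0.13 on KOF 1 to 3, and without KOF 3 it was called lower at -0.96 (adjusted p = 3.12e-05, 1.14e-06 to 0.584 over the alternatives). For the list itself, the fit with a control-shift block rests on KOF 3 alone, where the median over tested members was 0.09. The list's camera adjusted p ran up to 0.893 over the alternatives, and was 0.805 with an estimated correlation over all arrays. In the block fit the list member Ppp1r15a stood at -0.55. Hypoxia and glycolysis genes had an adjusted p of 0.351, with 7 higher and 2 lower of 22 at an unadjusted p under 0.05 and 2 rising when adjusted over the list alone, and Ldha and Tpi1 stood at 0.23 and 0.18. Oxidative stress genes had an adjusted p of 0.975, with 1 higher and 2 lower of 18, and Fth1 and Mt1 stood at 0.07 and 0.07 (-0.04 and -0.05 on KOF 3). The sex-linked genes Xist and Eif2s3y showed both sexes in each group, and their list had an adjusted p of 0.702, with 0 of 2 at an unadjusted p under 0.05. Eif2s3y was high on wild type 2, KOF 2 and KOF 3. The sex list had a median of 0.19 and a mean of -0.09, and the neural list 0.06 and -0.03.

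Camera called 10 of the 32 lists, 3 higher and 7 lower. With an estimated correlation it called 0, with 6 at an unadjusted p under 0.05. Adjusted over the list alone, 0 members passed in each list for which no such count is given above. Fry called 6 lists in 1 direction and 6 when changes in either direction counted. Those called in 1 direction were p53 targets, replication, erythroid, macrophage, megakaryocyte and stellate genes. Of the lists called by camera, those not called by fry in 1 direction were mitosis (adjusted p = 0.0578), checkpoint and homologous recombination (0.0644), B-lymphoid (0.0566) and interferon genes (0.234). With changes in either direction counted, fry called the B-lymphoid (adjusted p = 0.000266) and interferon lists (0.0203). It did not call mitosis (0.0976) or checkpoint and homologous recombination (0.109) in that form.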

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

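The test of RNA input or labelling, those of immune cells and embryo sex for interferon genes, and the count of sample splits for genes were chosen after the results were seen. Poly-A control RNAs, which lie outside the gene comparison, stood above the wild type arrays by a median log2 of 1.15 on KOF 1 and 1.07 on KOF 2, and the 18S ribosomal probe sets by 1.21 and 1.16. Among 5765 probe sets with no single gene symbol, 1 was called by limma, at a log2 of 1.17 (SE 0.11, adjusted p = 0.0406), and 764 had an unadjusted p under 0.05.

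KOF 1 and KOF 2 lay apart from the other 4 arrays over all genes. Degraded RNA in these samples would raise the 3' over 5' signal of polyadenylated control transcripts on both arrays. This was seen in 1 of 4 transcripts, pyruvate carboxylase (1.72 and 1.62, against at most 1.47 elsewhere). Actb and Gapdh, bright and with at most 0.18 on every array, may be unable to show it. The transferrin receptor itself was lower on KOF 1 and KOF 2 (3' signal 7.35 and 7.58, against 8.90 on KOF 3). The count therefore cannot exclude degradation. Hybridisation or scanning would move the hybridisation controls as much as genes of equal brightness, but their median change was 0.142 times that of such genes. Less RNA input or another labelling run remains a candidate explanation, because the lower of the medians of added poly-A RNAs on KOF 1 and KOF 2 was 1.07, with single probe sets from 0.87 to 1.41, while the median on KOF 3 was -0.06. A smaller poly-A share in the RNA of those embryos would give the same shift, and was not tested. Less input by itself would not move a sample's own 18S RNA against its other transcripts. The 18S probe sets stood at 1.21 and 1.16 on KOF 1 and KOF 2, against 0.10 on KOF 3, which argues against input as the only difference.

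Interferon-stimulated genes were highest on KOF 3, where immune cells from another source would raise macrophage, granulocyte or T and NK cell genes, and the highest of these medians on KOF 3 was 0.00224. Sex of the embryo is argued against by wild type 2 and KOF 2, which also showed Y-linked signal and whose higher list median was 0.202 against 1.04 on KOF 3. The KOF genotype may raise part of these genes in all KOF embryos, since 20 of 43 lay higher on all KOF arrays, against a median of 6 and a highest count of 17 in 10000 random lists matched on signal (share 0.0001, the smallest these lists can give). Random lists ignore that these genes move together, at an estimated correlation of 0.52 with which camera gave an adjusted p of 0.706 (up to 0.826 over the alternatives). Of 10 splits, 7 gave a camera p as small. By fry in 1 direction 1 did, the real one. Fry did not call the list in 1 direction (adjusted p = 0.234). It called the list with changes in either direction counted (fry adjusted p = 0.0203). The genotype therefore stays a hypothesis. This leaves open why KOF 3 stood above KOF 1 and KOF 2, while 5 of the 27 members called higher with the control shift as a block were called lower without KOF 3, and an infection or another difference between embryos was not tested.

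The 6 arrays make 10 splits, too few for a share under 0.05. For genes 1 split, the real one, gave as many calls (7, and 1 in the highest other), and for lists 6 splits did (10 in the real one, and 13 in the highest other). That highest list split sets wild type 1, wild type 3 and KOF 1 against the rest, and so parts the arrays by Y-linked signal. For the p53 list, 3 of the 10 splits gave a camera p as small, the real one included. By fry 1 did, the real one. A fit of the lists with embryo sex as a covariate was added after seeing the data. Its camera adjusted p was 0.000985 for p53 targets (up to 0.247 over the alternatives) and 0.000853 for interferon genes (up to 0.826). Both use the preset correlation. With an estimated correlation and no covariate the adjusted p was 0.128 and 0.706. Embryo sex as a covariate left the sizes of the 7 gene changes at a median of 1.02 times those without it, which argues against sex as their source, although 2 of 7 stayed called.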

How the results depend on the processing

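Settings chosen after seeing the data called 128 genes with the control shift as a block, 128 without KOF 1 and KOF 2, and 1 without wild type 1 and KOF 2. The count of called genes moved from 7 to 11 with all probe sets tested separately, 11 at an adjusted p under 0.1, 2 with embryo sex as a covariate, 10718 with array weights, and 2 to 9902 with each array left out in turn. The weight of KOF 3 was 0.0375, the lowest of the 6. Same-numbered deviations from the group means correlated at -0.02, 0.21 and 0.35. Deviations from a mean of 3 arrays depend on each other, so these values cannot settle whether the replicate numbers pair embryos. The replicate block gave 2 called genes. Rnaseh2b fell and passed under all 16 alternatives run, with log2 from -4.32 to -3.92. List calls moved from 10 to 0 with an estimated correlation and to 6 with fry. The p53 adjusted p was 0.128 with an estimated correlation and ran from 6.49e-07 to 0.247 with single arrays left out. For interferon genes it was 0.706, 0.234 with fry, and 1.03e-12 to 0.826. Cela1 turned to 0.14 with array weights (adjusted p = 0.0492), and the hepatoblast list turned higher with the control shift as a block (0.00691) and without KOF 1 and KOF 2 (0.00810). The cause was not tested. Of 1511 alternative values for named genes 1354 neither lost nor gained a call, 91 uncalled values among them turning sign, 40 lost and 116 gained one, and of 544 for lists 512 (36 turning sign), 17 and 13. Deposited and median-centred values each called 9 genes, including all 7. An unmoderated linear model called 6 genes, of which 2, Rnaseh2b and Psrc1, were among the 7. A floor for linear values was not run, because the table holds log values. The number of arrays limits all of these, and signal over background was not analysed here.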

Other observations

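The genes and tests in this part were chosen after their values were seen, apart from the fits without a single array. With the control shift as a block, 128 genes were called, 86 higher and 42 lower in KOF, of which 47 belong to a fixed list and 81 to none. Of the 128, 32 lay on the other side of the wild type mean on both KOF 1 and KOF 2, and 18 were called in the other direction without KOF 3. Of those in no list, Trim34a was higher on KOF 3 by 1.96 (SE 0.08), Parp9 by 1.93 (SE 0.09) and Rnf213 by 2.11 (SE 0.12), while their pooled differences over all 6 arrays were 0.49, 0.30 and 0.96 and did not pass (adjusted p = 0.553, 0.744 and 0.1999). Without KOF 3, Trim34a was called lower (-0.24, adjusted p = 0.0102), as was Parp9 (-0.52, adjusted p = 0.000377), and Rnf213 was called higher (0.39, adjusted p = 0.0061). Cyp3a11 and Tac2 below were called lower both with the block and without KOF 3. Among genes lower in that fit were Cyp3a11, a cytochrome of drug metabolism, at -1.38 (SE 0.14, adjusted p with the block = 0.00707), and Tac2, a tachykinin precursor, at -1.43 (SE 0.16, adjusted p with the block = 0.00772).

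Muscle genes varied within both groups. The median of 18 measured members was 1.00, -0.45 and -0.56 on wild type 1 to 3 and -0.50, 1.41 and -0.02 on KOF 1 to 3, as log2 minus the wild type mean. Cardiac actin, Actc1, stood at -1.48, 3.67 and 0.62 on KOF 1 to 3. Without wild type 1 the muscle list had a camera adjusted p of 0.00363, without KOF 1 one of 0.0203, and without wild type 1 and KOF 2 together one of 0.00499, in a range of 0.00363 to 0.967 over its alternatives. These use the preset correlation, and with the estimated correlation of this list, 0.807 over all arrays, its adjusted p was 0.912. Without that pair of arrays 1 gene was called between the groups, Rnaseh2b.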
